A study of Mus musculus with 6 samples.

How the data were processed

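Gene expression was measured in 6 samples of sorted mouse small-cell lung cancer cells, 3 GFP-high and 3 GFP-negative, per the labels. Tumours were collected 5 to 6 months after Cre and pooled, and the treatment protocol speaks of pools from 3 mice. RNA was extracted with a Qiagen AllPrep micro kit and labelled with the Affymetrix WT Plus and WT Terminal Labeling kits for the Mouse Gene 2.0 ST array, per the labels' protocols. Samples of a group are titled as biological replicates, but whether each came from its own pool of mice, and whether GFP-high and GFP-negative samples of the same number came from the same pool, is not given in the sources used here. The p-values therefore measure the spread between these samples. The gates of the sort, and any exclusion of leukocytes or endothelial cells before it, are likewise not given in the sources used here.

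The deposited values are log2 expression values made by the authors with RMA, which corrects background, equalises the distribution of arrays and summarises probes, per the submitters' processing notes; its version and annotation release are not given in the sources used here. The log2 scale follows from the values, which run from 0.989 to 13.72 with array medians between 5.30 and 5.43. Because RMA equalises the distributions of the arrays, a shift shared by most genes would not be seen, and folds near the lower end of the scale are compressed. The table has 41344 rows. The platform annotation names exactly 1 gene for 23520 rows, several genes for 1814 and no gene for 16010. The Entrez identifiers of 23327 single-gene rows were found in the RefSeq gene table, which changed 0 symbols. A gene with several rows, true of 1082 genes, was represented by its row with the highest mean over all arrays, which left 22179 genes. Rows naming several genes or none were not used in the main comparison. No gene was left out for a low level, and 0 columns of the table belonged to other samples.

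Values were compared with limma (lmFit and eBayes with default settings, moderated by 4.50 prior degrees of freedom on 4 residual ones), without a block, as GFP-high minus GFP-negative. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested, with calls at an adjusted p under 0.05. A permutation of 3 against 3 samples cannot give a p below 0.10, so no permutation p is reported. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

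Before the data were examined, 35 gene lists were fixed: 20 tumour cell lists and 15 cell type marker lists. Of their 533 places 493 were measured, and 40 were not analysed here. Lists with at least 5 measured members (34) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists tested. With a preset correlation 11 lists passed as higher and 4 as lower, and with a correlation estimated from these 6 arrays 0 passed, so each such p is given beside its list. The estimated form also uses only the 4 residual degrees of freedom of the fit, so its p-values do not reflect correlation alone. Counts called adjusted over the list alone come from the same p-values adjusted within a list. A list's median is over the log2 fold changes of its measured members. The genes named in the text follow a rule also fixed beforehand. It takes a panel of 21 genes, of which 19 were measured, and in each direction the 6 largest changes among called genes with non-overlapping groups, leaving out unannotated gene models, predicted and small RNA genes. It adds up to 4 members of each list with the largest absolute change.

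On simulated data with the spread of these arrays and 22179 genes, for the comparison of GFP-high with GFP-negative, limma recovered 2% of 50 genes changed by 0.5 on the log2 scale, 74% of 50 changed by 1, 98% of 50 changed by 2 and 100% of 50 changed by 3. Few genes were changed there beside the 30.0% called in the data, which makes the adjusted threshold stricter in the simulation. The recovered shares therefore do not carry over to the data. In that simulation 14 of 151 calls (9.27%) were false. Over 20 such simulations the share of false calls averaged 4.65% (1.43% to 8%). A list shifted in simulated data, the mitosis genes, was found by camera, and no other list was called. The simulated genes were drawn independently of each other, whereas the estimated correlation of that list in the data was 0.83. The simulation therefore does not check the list p-values for correlated genes.

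Alternatives, fixed with the lists, were per-array median centring, quantile normalization, leaving out the lowest 30% of genes, the mean of all rows of a gene, every row on its own, eBayes with trend and robust settings, array weights, the replicate number as a block, leaving out each array, a per-gene test without moderation, a minimum absolute log2 fold change of 1, camera with an estimated correlation, fry, and lists without shared members.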

Results

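Mouse small-cell lung cancer was sampled from a model in which intratracheal adenovirus carrying Cre deletes conditional alleles of Rb1, p53 and p130 (Rbl2) in the lung. The animals also carried an allele that reports expression of Hes1, a transcriptional repressor induced by Notch signalling, as green fluorescence. Tumours taken 5 to 6 months after Cre were pooled and sorted by flow cytometry into GFP-negative and GFP-high cells. Total RNA from 3 samples of each population was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, giving 6 arrays and a single comparison: which genes differ between the Hes1-reporting and non-reporting cells of these tumours. The number of arrays, 3 per group, limits the precision. Log2 expression values correlated at 0.987 to 0.991 between arrays of the same group and at 0.918 to 0.940 between groups, across 22179 genes that are not independent of each other. The first principal component held 82.0% of the variance and separated the groups, with GFP-high replicate 3 at 46.9 and the other GFP-high arrays at 60.8 and 62.5.

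Hes1 followed the sort. Its log2 value was 10.40 ± 0.11 (SD, n = 3) in GFP-high cells and 6.85 ± 0.18 (SD, n = 3) in GFP-negative cells, an 11.7-fold difference (log2 fold change 3.54 ± 0.13 SE, adjusted p = 4.87e-07). The 3 GFP-high arrays read 10.49, 10.27 and 10.43, and the 3 GFP-negative arrays 6.93, 6.98 and 6.65. Rb1, the retinoblastoma gene, was lower in GFP-high cells (9.19 ± 0.39 against 10.79 ± 0.10; SD, n = 3 each; adjusted p = 0.000288), while its relatives Rbl2 and Rbl1 were higher by 0.53 ± 0.12 and 0.45 ± 0.12 (log2 fold change ± SE). Rb1 read 9.10, 8.86 and 9.62 in the GFP-high arrays and 10.87, 10.68 and 10.81 in the GFP-negative arrays. Rbl2 read 8.26, 8.41 and 8.23 in the GFP-high arrays and 7.92, 7.66 and 7.74 in the GFP-negative arrays. The position of these probes relative to the deleted exons is not given in the sources used here, so the values do not check the deletions. The call for Rbl1 (adjusted p = 0.0231) was lost without GFP-negative replicate 1 (0.0653), without GFP-negative replicate 2 (0.0731) or without GFP-high replicate 1 (0.0862).

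**Figure D1:**
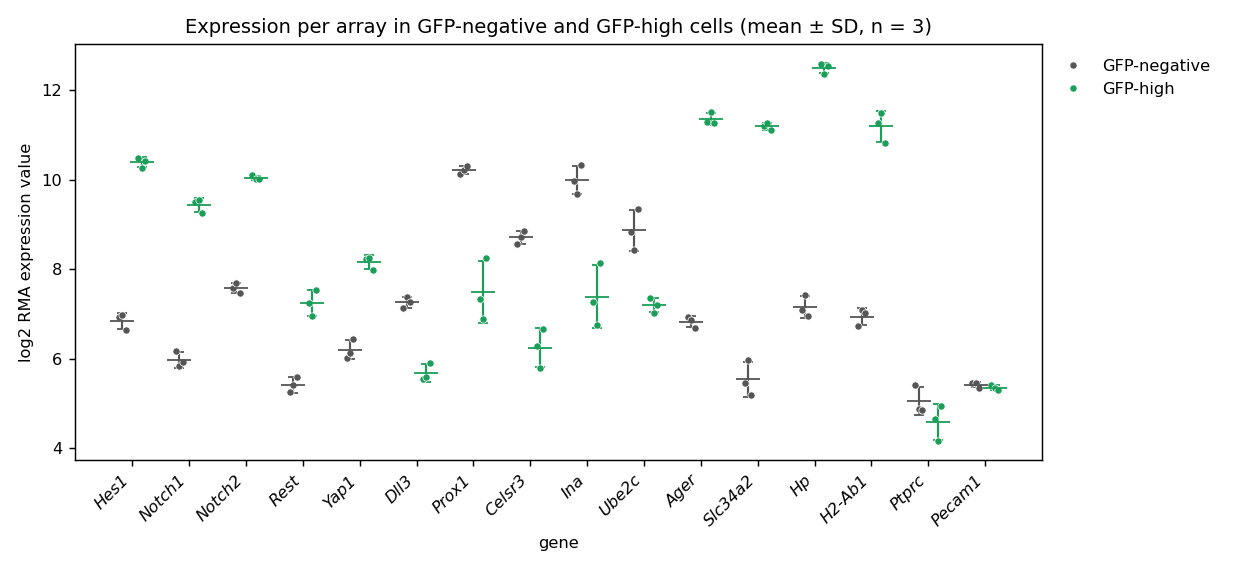
Log2 RMA expression values (vertical axis) of 16 genes in the 3 GFP-negative arrays (grey) and the 3 GFP-high arrays (green); points are arrays, horizontal marks are means and bars are SDs. Hes1 sits near 10.40 in GFP-high and 6.85 in GFP-negative cells, Prox1 falls from 10.22 to 7.49, and the leukocyte gene Ptprc and the endothelial gene Pecam1 overlap between the groups.

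Across the array, 6661 of 22179 genes (30%) differed between the groups at an adjusted p under 0.05: 2888 were higher in GFP-high cells and 3773 were lower. The 6 largest rises among annotated genes were those of Fmo2, a flavin monooxygenase (5.77 ± 0.26), Lamp3, a lamellar body protein (5.76 ± 0.14), Pon1, a paraoxonase (5.76 ± 0.19), the phosphate transporter Slc34a2 (5.65 ± 0.19), the lung chemokine Cxcl15 (5.63 ± 0.22) and the cholecystokinin receptor Cckar (5.60 ± 0.21; all log2 fold change ± SE, n = 3 per group). The 6 largest falls were those of the neuronal RNA-binding protein Elavl3 (-3.17 ± 0.34), Clca3a2 (-3.05 ± 0.30), the calcium channel subunits Cacna2d1 (-2.96 ± 0.25) and Cacng7 (-2.91 ± 0.36), the neuronal serpin Serpini1 (-2.87 ± 0.29) and Gdap1 (-2.82 ± 0.34). Rises reached further than falls: 232 genes were higher by a log2 fold change of at least 3 and 2 were lower by as much, while 1249 rose and 1335 fell by at least 1. Of the 161 genes chosen by the fixed rule, 132 passed the threshold, and in 131 of these the 3 values of one group all lay on the same side of the other group's. The rule picks large changes in these same arrays, so these counts are largely built in and are no evidence of separation. Over all genes the groups did not overlap for 9897 (44.6%), against 10% by chance for 3 against 3. A per-gene test without moderation called 2302 genes, and 59 of the named genes lost their call in it, among them Rb1, Myc, Prox1, Ncam1, Bmp4, Cdh2, Fn1, Sftpb and Cacna2d1.

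**Figure D2:**
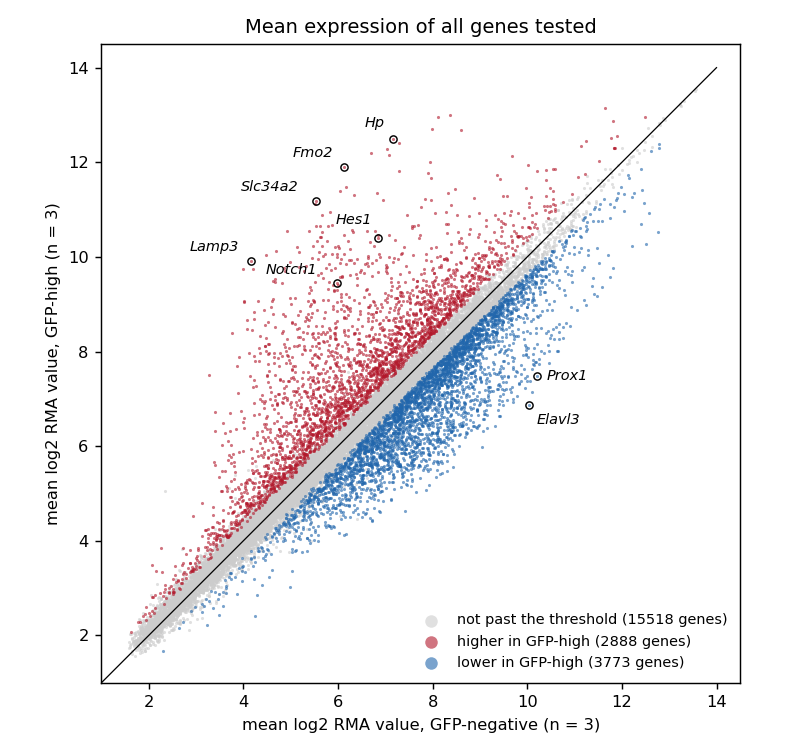
Mean log2 RMA value in GFP-negative arrays (horizontal axis, n = 3) against GFP-high arrays (vertical axis, n = 3) for the 22179 genes tested, with 2888 genes higher in GFP-high in red, 3773 lower in blue and the rest in grey; the line marks equality. The points above the line reach further from it, up to a log2 fold change of 5.77 for Fmo2, than those below, which end at -3.17 for Elavl3.

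Genes of the Notch pathway changed in both directions. Notch1 rose by 3.46 ± 0.14 on the log2 scale (11.0-fold, adjusted p = 7.44e-07), Notch3 by 2.81 ± 0.14 and Notch2 by 2.46 ± 0.11. The inhibitory ligand Dll3 (-1.57 ± 0.13) and the neuronal Notch ligand Dner (-2.51 ± 0.23) fell. The ligand Jag1 rose (0.78 ± 0.13), while the ligands Dll4 (-1.87 ± 0.24), Dll1 (-1.80 ± 0.17) and Jag2 (-1.56 ± 0.14) fell. The modifiers Lfng (-1.91 ± 0.14) and Mfng (-1.89 ± 0.17) fell too, and the receptor Notch4 did not pass (-0.21 ± 0.14, adjusted p = 0.333). The genes from Jag1 to Notch4 are named here after their values were seen. Of 14 measured ligands, receptors and modifiers, 4 were higher, 7 lower and 3 did not pass, with the same counts adjusted over the list alone. The list as a whole had no common direction (median -0.88, adjusted p = 0.25 by camera). Of 11 measured Notch target genes other than Hes1, 7 were higher and 2 lower, with the same counts adjusted over the list alone. Hey2 (0.92 ± 0.12) and Hes5 (0.43 ± 0.11) rose. Hey1 (0.21 ± 0.14, adjusted p = 0.317 by limma) and Heyl (0.15 ± 0.13, adjusted p = 0.449 by limma) did not pass. These Hes and Hey genes are named here after their values were seen. Sox9, a transcription factor of epithelial progenitors, rose by 4.29 ± 0.17 and Nrarp, a feedback inhibitor of Notch, by 1.89 ± 0.11, while the E3 ligase gene Dtx1 (-1.37 ± 0.22) and Myc (-0.96 ± 0.14) fell. The target list passed the test (median 0.85, adjusted p = 0.000967; adjusted p = 0.138 with an estimated correlation). Notch3 belongs to both lists. Mycn (-0.28 ± 0.12, adjusted p = 0.12) and Mycl (-0.01 ± 0.15, adjusted p = 0.972) did not pass. Markers of club and secretory, alveolar type 2 and alveolar type 1 cells were higher in the same GFP-high arrays, with list medians of 4.20, 3.06 and 1.99.

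Neuroendocrine and neuronal genes were lower in GFP-high cells, where the transcriptional repressor Rest was higher (1.83 ± 0.17, 3.56-fold, adjusted p = 8.16e-05). Of 22 measured neuroendocrine markers, 19 fell, 1 rose and 2 did not pass, and adjusted over the list alone the counts were the same. The homeobox gene Prox1 fell by 2.72 ± 0.30, the adhesion molecule Ncam1 by 2.67 ± 0.35 and the granin Scg3 by 2.62 ± 0.32 on the log2 scale. The exception was Nkx2-1, a lung lineage transcription factor, which rose by 0.79 ± 0.13, and Neurod1 stayed near 4.31 in GFP-high and 4.17 in GFP-negative cells (adjusted p = 0.463). The list median was -2.07 (adjusted p = 1.81e-09; adjusted p = 0.293 with an estimated correlation). Of 21 measured neuronal genes repressed by REST, 17 fell, none rose and 4 did not pass; adjusted over the list alone, 19 fell. Among them Ina, an intermediate filament protein, fell by 2.61 ± 0.32, the cadherin Celsr3 by 2.46 ± 0.21 and Rundc3a by 2.22 ± 0.19. This list had a median of -1.78 (adjusted p = 2.04e-10; adjusted p = 0.223 with an estimated correlation). Uchl1 and Rab3c, also among the falls, each had a second row on the array that did not move (0.03 and 0.01). GFP-high replicate 3 stood apart: its median difference from the GFP-negative mean was -1.40 over the neuroendocrine markers, against -2.27 and -2.54 in the other GFP-high arrays. Without that array 6116 genes were called. Club, alveolar type 2 and alveolar type 1 markers moved the other way in the same arrays (list medians 4.20, 3.06 and 1.99).

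YAP and TAZ, coactivators of the Hippo pathway, were higher together with most of their targets. Of 18 measured members 16 rose, none fell and 2 did not pass, with the same counts adjusted over the list alone (median 1.68, adjusted p = 5.47e-11; adjusted p = 0.138 with an estimated correlation). Wwtr1, which encodes TAZ, rose by 3.56 ± 0.14, Yap1 by 1.96 ± 0.15, Ajuba by 3.05 ± 0.16 and the matricellular gene Ccn1 by 3.03 ± 0.26. A second row for Yap1, at a lower level, rose by 0.50. Basement membrane and integrin genes were also higher, with 11 of 19 up, 1 down and 7 not passing, and 11 up and 2 down adjusted over the list alone (median 0.80, adjusted p = 4.87e-05; adjusted p = 0.195 with an estimated correlation). The laminin genes Lamb2 (3.49 ± 0.12), Lamb3 (3.00 ± 0.17) and Lama5 (2.79 ± 0.15) and the integrin Itga2 (2.85 ± 0.19) led that list. Mesenchymal genes split: Sparc (4.18 ± 0.12), Fn1 (2.39 ± 0.28) and Cd44 (2.22 ± 0.18) rose and N-cadherin, Cdh2, fell (-2.73 ± 0.27). The counts were 4 up, 3 down and 9 not passing of 16 (5 up and 3 down adjusted over the list alone; median 0.25, adjusted p = 0.167). Epithelial genes split as well, 4 up and 4 down of 20 (4 up and 5 down adjusted over the list alone; adjusted p = 0.691). Their median was -0.13 and their mean 0.06, opposite in sign. Keratin 19, Krt19, rose by 3.14 ± 0.30 and Grhl2 by 1.37 ± 0.14, and the claudin Cldn4 fell (-1.47 ± 0.23). Epcam fell by 0.49 ± 0.13 on the log2 scale (10.33 ± 0.14 against 10.83 ± 0.15; SD, n = 3 each; adjusted p = 0.0192). That call was lost without GFP-negative replicate 1 (0.0751) or GFP-high replicate 2 (0.0660). Club, alveolar type 2 and alveolar type 1 markers rose in these arrays too, with list medians of 4.20, 3.06 and 1.99.

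Cell cycle genes were lower in GFP-high cells. All 20 measured mitosis genes fell, also when adjusted over the list alone (median -1.26, adjusted p = 1.00e-10; adjusted p = 0.358 with an estimated correlation). The ubiquitin-conjugating enzyme Ube2c fell by 1.67 ± 0.22, cyclin A2 (Ccna2) by 1.65 ± 0.19, and the mitotic kinases Bub1 and Plk1 by 1.49 ± 0.16 and 1.48 ± 0.17. Of 19 DNA replication genes 14 fell and none was higher, with the same counts adjusted over the list alone (median -0.49, adjusted p = 7.21e-06; adjusted p = 0.385 with an estimated correlation). The ribonucleotide reductase genes Rrm2 (-1.31 ± 0.23) and Rrm1 (-1.01 ± 0.12), cyclin E1 (Ccne1, -1.14 ± 0.15) and the helicase gene Mcm2 (-1.06 ± 0.14) led it. A second row for Rrm2 gave -0.44 and did not pass. The p53 target genes had no common direction, with 4 up, 5 down and 6 not passing of 15 and the same counts adjusted over the list alone (median -0.18, adjusted p = 0.691). The death receptor Fas rose by 3.24 ± 0.18, and the cell cycle inhibitor Cdkn1a (-1.29 ± 0.17), Eda2r (-1.44 ± 0.19) and Plk2 (-1.41 ± 0.25) fell. Club, alveolar type 2 and alveolar type 1 markers were higher in the same GFP-high arrays, with list medians of 4.20, 3.06 and 1.99.

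Genes of the TGF-beta and BMP response were higher on balance, 8 up, 3 down and 3 not passing of 14, or 10 up and 3 down adjusted over the list alone (median 0.62, adjusted p = 0.0179; adjusted p = 0.358 with an estimated correlation). The ligand Tgfb2 rose by 3.11 ± 0.23 and the inhibitory Smad6 and Smad7 by 1.98 ± 0.15 and 1.59 ± 0.13, while the ligand Tgfb1 fell (-1.58 ± 0.22). Club and alveolar type 2 markers, with list medians of 4.20 and 3.06, and alveolar type 1 markers, with 1.99, were higher in these arrays too. Secreted growth factors and cytokines did not move as a list (5 up, 5 down, 11 not passing of 21, the same counts adjusted over the list alone; median 0.13, adjusted p = 0.518). Single members changed strongly. Bmp4 rose from 5.63 ± 0.71 to 10.64 ± 0.10 (SD, n = 3 each; adjusted p = 7.09e-06), Il6 rose by 2.05 ± 0.35 and Mdk, encoding midkine, by 1.16 ± 0.11 on the log2 scale. Hgf (-2.51 ± 0.27) and pleiotrophin, Ptn (-2.30 ± 0.24), fell. Immediate early and dissociation stress genes, which mark handling of live cells, were 4 up, 9 down and 9 not passing of 22, with the same counts adjusted over the list alone (median -0.19, adjusted p = 0.25). Ier3 (2.96 ± 0.19) and the heat shock genes Hspa1b (2.06 ± 0.33) and Hspa1a (1.72 ± 0.30) rose and Egr3 fell (-2.11 ± 0.21). Hypoxia and glycolysis genes had 2 up and 6 down of 14, the same counts adjusted over the list alone (median -0.10, adjusted p = 0.25). They included a rise of Vegfa (1.92 ± 0.12) and falls of the glucose transporter Slc2a1 (-1.05 ± 0.14) and Egln3 (-1.78 ± 0.28). A second row for Slc2a1 gave -0.37 and did not pass (adjusted p = 0.0576). Of 19 oxidative phosphorylation genes 3 fell and 16 did not pass, and none passed adjusted over the list alone (median -0.13, adjusted p = 0.239). Tuft cell genes did not move as a list (1 up and 1 down of 11, the same counts adjusted over the list alone; median 0.03, adjusted p = 0.691). Dclk1, a kinase used as a tuft cell marker, rose by 2.38 ± 0.24.

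Antigen presentation genes were higher in GFP-high cells. Of 7 measured MHC class II genes 6 rose, and all 7 adjusted over the list alone. H2-Ab1 rose by 4.25 ± 0.18 (11.19 ± 0.34 against 6.94 ± 0.19; SD, n = 3 each; adjusted p = 1.09e-06), H2-Aa by 4.05 ± 0.15 and H2-Eb1 by 2.06 ± 0.21. The class II list had a median of 1.81 (adjusted p = 3.68e-06; adjusted p = 0.138 with an estimated correlation). MHC class I presentation genes rose in 9 of 11, with the same count adjusted over the list alone (median 0.82, adjusted p = 9.46e-06; adjusted p = 0.283 with an estimated correlation). The immunoproteasome subunit Psmb10 (1.38 ± 0.14) and H2-K1 (1.11 ± 0.16) led them. Interferon response genes were 8 up, 1 down and 4 not passing of 13, with the same counts adjusted over the list alone (median 0.65, adjusted p = 0.000894; adjusted p = 0.205 with an estimated correlation). Bst2 rose by 2.19 ± 0.12 and Isg15 by 2.18 ± 0.15. Pan-leukocyte markers, measured in the same arrays, were 1 down and 9 not passing of 10. Club, alveolar type 2 and alveolar type 1 markers were higher there, with list medians of 4.20, 3.06 and 1.99.

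The highest list medians were those of club, alveolar type 2 and alveolar type 1 markers. Of 12 measured club and secretory cell markers 10 rose, 1 fell and 1 did not pass, or 11 up and 1 down adjusted over the list alone (median 4.20, adjusted p = 5.55e-10; adjusted p = 0.195 with an estimated correlation). Haptoglobin (Hp) rose by 5.34 ± 0.14, Gabrp by 5.24 ± 0.22, the secretoglobin Scgb3a1 by 5.11 ± 0.32 and the carbonyl reductase Cbr2 by 4.73 ± 0.21. The member that fell, Aldh1a7 (log2 fold change -0.92), is named here after its value was seen. Of 12 alveolar type 2 markers 11 rose and 1 did not pass, with the same counts adjusted over the list alone (median 3.06, adjusted p = 2.04e-10; adjusted p = 0.138 with an estimated correlation). They include Lamp3, Slc34a2 and Cxcl15 above and the surfactant protein gene Sftpb (4.85 ± 0.30). All 10 alveolar type 1 markers rose, also adjusted over the list alone (median 1.99, adjusted p = 5.55e-10; adjusted p = 0.138 with an estimated correlation), led by Ager (4.53 ± 0.12) and the aquaporin Aqp5 (4.22 ± 0.17). Vegfa is in this list and in the hypoxia list. GFP-high replicate 3 had the highest alveolar type 2 median, 3.90 above the GFP-negative mean, against 2.61 and 2.84 in the other GFP-high arrays, while its club median of 4.14 was close to theirs (4.28 and 4.17). Ciliated cell markers did not move as a list (2 up, 2 down, 7 not passing of 11, or 3 up and 2 down adjusted over the list alone; median 0.28, adjusted p = 0.432). Dynlrb2 rose by 3.10 ± 0.19. Basal cell markers had 2 up and 5 not passing of 7, with the same counts adjusted over the list alone (median 0.12, adjusted p = 0.314). Both were at low levels, such as the aquaporin Aqp3 (5.45 ± 0.19 against 4.45 ± 0.19; SD, n = 3 each).

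**Figure D3:**
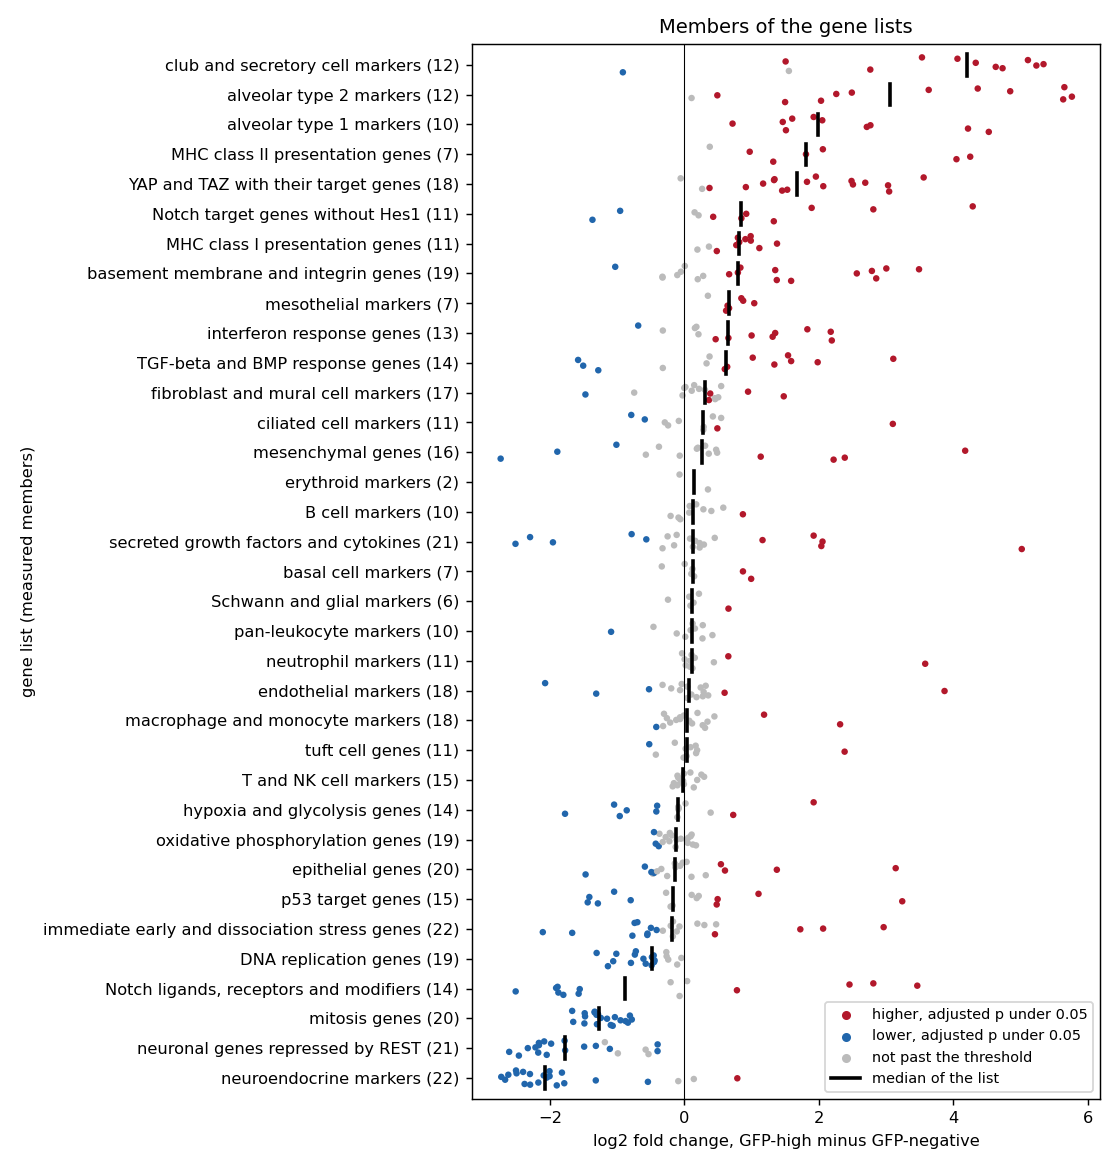
Log2 fold change, GFP-high minus GFP-negative, of every measured member (points) of the 35 fixed gene lists, ordered by list median (black bars), with members higher at an adjusted p under 0.05 in red, lower in blue and others in grey. Club, alveolar type 2 and alveolar type 1 markers have the highest medians (4.20, 3.06 and 1.99) and neuroendocrine markers and REST-repressed neuronal genes the lowest (-2.07 and -1.78).

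Of the marker lists for cells outside the lung epithelium, the mesothelial list passed the test. No leukocyte list passed the test. Pan-leukocyte markers had 0 up and 1 down of 10 (median 0.11, adjusted p = 0.768), and macrophage and monocyte markers 2 up and 1 down of 18 (median 0.03, adjusted p = 0.5). Neutrophil markers had 2 up of 11 (median 0.11, adjusted p = 0.167) and B cell markers 1 up of 10 (median 0.13, adjusted p = 0.25). None of 15 T and NK cell markers passed (adjusted p = 0.806), with a median of -0.02 and a mean of 0.01, opposite in sign. Adjusted over the list alone, the macrophage list had 2 up and 0 down, the neutrophil list 1 up, and the other leukocyte counts stayed as given. Ptprc, which encodes CD45, differed by -0.46 ± 0.23 (adjusted p = 0.17), and the mean of the pan-leukocyte list was -0.03, opposite in sign to its median. Single members stood out, including Cd14 (2.32 ± 0.22), Mpeg1 (1.18 ± 0.25), the iron-binding protein gene Ltf (3.58 ± 0.20) and Cd79b (0.87 ± 0.12), which rose, and Coro1a (-1.09 ± 0.20), which fell. Endothelial markers were 2 up, 3 down and 13 not passing of 18, with the same counts adjusted over the list alone (median 0.07, adjusted p = 0.632). Pecam1 stayed level (5.36 ± 0.05 against 5.42 ± 0.06; SD, n = 3 each; adjusted p = 0.698), Kdr, which encodes a VEGF receptor, rose by 3.87 ± 0.13, and Vwf (-2.07 ± 0.23) and Erg (-1.31 ± 0.12) fell. Fibroblast and mural cell markers were 4 up, 1 down and 12 not passing of 17, or 2 up and 1 down adjusted over the list alone (median 0.31, adjusted p = 0.073). Col6a3 rose by 1.48 ± 0.13, and the member that fell was Dcn (-1.47 ± 0.38). The fibroblast list passed without GFP-negative replicate 3 (adjusted p = 0.0462), GFP-high replicate 1 (0.0348) or GFP-high replicate 2 (0.0135), and reached 0.432 without GFP-high replicate 3. Mesothelial markers rose in 6 of 7, and in all 7 adjusted over the list alone (median 0.66, adjusted p = 0.000967; adjusted p = 0.293 with an estimated correlation), led by Rspo1 (1.04 ± 0.13). Schwann and glial markers had 1 up of 6, also adjusted over the list alone (median 0.11, adjusted p = 0.518). Of the erythroid markers 2 were measured, too few to test; neither passed, and 1 was up adjusted over the list alone.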

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

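The tests of cell mixture, of the lower end of the scale and of leukocytes were chosen after the fold changes had been seen; the count over other splits of the arrays was set beforehand.

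Rows of the array outside the main comparison changed in both directions when every row was tested on its own. Of 16010 rows naming no gene, 776 were higher and 878 lower in GFP-high cells, and of 1814 rows naming several genes, 195 were higher and 205 lower. The largest rise among rows naming no gene was 5.23 on the log2 scale (11.48 against 6.25, adjusted p = 1.74e-05 by limma).

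The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 6661 genes, was the 1 split with as many, and the highest of the others called 0. Every other split mixes GFP-high and GFP-negative arrays, which puts their difference into the spread within groups. Few calls there were therefore built in, and the contrast does not show what chance would give.

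Club, alveolar type 2 and alveolar type 1 markers rose together in GFP-high cells, which may reflect normal lung epithelium in the sort or a change of state in tumour cells. A GFP-high sort made up wholly of quiescent normal cells plus carried-over neuroendocrine tumour cells would make mitosis genes fall at least as far as neuroendocrine and neuronal genes. The neural genes used for this included Nkx2-1, which rose (0.79), and Foxa2, which fell less than most of the others (-0.54). Against the neural gene nearest in GFP-negative level, the 20 mitosis genes fell less, by a median of 0.93, 0.78 and 0.26 in the 3 GFP-high arrays, but the mean of 0.66 had a 95% interval over the arrays from -0.22 to 1.54, so this mixture is not excluded. A normal admixture of part of the sort cannot be told apart from a change of state in these bulk arrays either: ciliated markers, which normal airway could bring along, had a median of 0.28 with members on both sides. A non-neuroendocrine tumour cell state stays open as well and was not tested.

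Large rises outnumbered large falls, 232 against 2 at an absolute log2 fold change of 3. Abundant neuroendocrine and neuronal genes did not reach the lower end of the array scale. The 20 with a GFP-negative mean of at least 9 still had a median GFP-high mean of 7.995, above the table median of 5.39. The lowest GFP-high mean among them was 6.86. For these 20 genes the values argue against the lower end of the scale as the limit of the falls. Genes with a lower GFP-negative mean were not part of this check, and no gene tested fell further than -3.17. Neuroendocrine cells carried over into the GFP-high sort could instead limit the falls, and would make these 20 genes fall alike. The SD of their log2 fold changes was 0.82, against 0.65 for 780 other genes called lower at that level, but Nkx2-1 and Foxa2 (named after their values were seen) set it, and without them it was 0.26, so this test does not decide. A partial loss of neuroendocrine expression in every GFP-high cell would give the same values and was not tested. The median difference of the 20 genes from the GFP-negative mean was -2.52, -2.72 and -1.72 in GFP-high replicates 1, 2 and 3.

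MHC class II genes rose by a median of 1.81. Leukocytes as the whole source would bring their other transcripts with them by about as much, but 38 pan-leukocyte, macrophage and B cell markers had a median of 0.085 (SD of their log2 fold changes 0.53), which argues against that. Median levels of the pan-leukocyte markers (5.20 in GFP-high, 5.17 in GFP-negative) and B cell markers (4.82 and 4.80) lay below the table median of 5.39. Those of the macrophage markers lay above it (5.85 and 5.71). Folds near the lower end of the scale are compressed. Of the 38 markers, 3 were higher, Cd14 (2.32), Mpeg1 (1.18) and Cd79b (0.87), and 2 were lower. A smaller contribution by leukocytes therefore stays open. Expression by alveolar type 2 cells or by tumour cells in a changed state stays open too; the bulk values do not separate these, and neither was tested.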

How the results depend on the processing

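All alternatives were set in advance. Hes1 kept its call in each of them, with log2 fold changes from 3.44 to 3.61. Counts of genes called stayed within 1.5 times of 2888 higher and 3773 lower, except in a per-gene test without moderation (1193 higher, 1109 lower) and with a minimum absolute log2 fold change of 1 (1249 higher, 1335 lower); fewer degrees of freedom and a stricter rule are built into these. Leaving out 1 array gave 5408 to 6116 genes called. The other scalings moved the share of higher calls from 43.4% to 41.8% and 45.9%.

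The main fit had no block because the labels state no pairing of same-numbered samples. Same-numbered arrays deviated together by correlations of 0.11, -0.03 and -0.0016. Of 3 GFP-negative arrays, 1 correlated best with the GFP-high array of its number. With 3 arrays per group these correlations do not settle whether the samples are paired. With the replicate block 6172 genes were called (2729 higher, 3443 lower), 5964 of them among the 6661, and the fibroblast list passed (adjusted p = 0.0445).

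With an estimated correlation all 15 list calls were lost. That form of the test also uses only the 4 residual degrees of freedom, so the loss does not reflect correlation alone. For Notch targets the estimated correlation was -0.029, below the preset 0.01, and the call was still lost. The adjusted p was 0.138 for Notch targets, YAP and TAZ, MHC class II, alveolar type 2 and alveolar type 1, 0.195 for basement membrane and club, 0.205 for interferon, 0.223 for REST-repressed, 0.283 for MHC class I, 0.293 for neuroendocrine and mesothelial, 0.358 for mitosis and TGF-beta, and 0.385 for DNA replication. By fry, which does not set a list against other genes, further lists passed: mesenchymal (0.00801), secreted factors (0.0078), endothelial (0.000913), neutrophil (0.00727) and B cell (0.0299). The fibroblast list ran from 0.0135 to 0.432 when 1 array was left out; the cause was not tested. Outside these alternatives no list changed its side of the threshold.

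Of 160 named genes besides Hes1, 66 changed their side of the threshold in at least 1 alternative, 59 of them in the test without moderation, and 0 reversed. Genes whose values lie near the lower end of the scale have compressed folds. Changes of 0.5 on the log2 scale were rarely recovered in simulation, where far fewer genes changed than were called here. In these arrays some changes of about that size passed, such as Rbl2 (0.53, adjusted p = 0.00997 by limma). Others did not, such as Sntn (0.55, adjusted p = 0.0597 by limma).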

Other observations

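The families below, and the members named, were chosen after the fold changes had been seen.

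Genes were grouped by the letters their symbols share, and the 127 families with at least 15 measured members were tested with camera at the preset correlation; 9 passed. Clustered protocadherins of the beta family, cell surface proteins of neurons, were the most uniform: 18 of 22 Pcdhb genes were lower in GFP-high cells and none higher (median -1.05, adjusted p = 8.80e-09; adjusted p = 0.55 with an estimated correlation), led by Pcdhb17 (-2.80 ± 0.25) and Pcdhb15 (-2.27 ± 0.25). Median centring and quantile normalization each gave 19 lower. Of 17 synaptotagmin (Syt) genes, 12 were lower and 2 higher (median -1.44, adjusted p = 0.00232; adjusted p = 0.55 with an estimated correlation), and Syt14 fell by 2.04 ± 0.16 on the log2 scale. Of 16 genes with the Mapk symbol, 9 were lower and none higher (median -0.58, adjusted p = 0.00176; adjusted p = 0.55 with an estimated correlation), among them the neuronal kinase Mapk10 (-1.75 ± 0.21). These 3 families passed in the other scalings as well.

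Collagen genes were more often higher, 11 of 44 with 3 lower (adjusted p = 0.0221, and 0.0488 after quantile normalization; adjusted p = 0.721 with an estimated correlation). Col23a1 rose by 3.39 ± 0.18 and Col15a1 by 3.33 ± 0.16, while Col8a1 fell by 2.19 ± 0.22 on the log2 scale. Cytochrome P450 genes had 17 higher and 3 lower of 94 (adjusted p = 0.0251, and 0.116 after quantile normalization, where the call was lost; adjusted p = 0.55 with an estimated correlation), with Cyp4b1 (5.22 ± 0.23), Cyp4f15 (5.03 ± 0.28) and Cyp2b10 (4.59 ± 0.13) among the rises. Kinesins split by member: Kif1a (-2.49 ± 0.23) and Kif5c (-1.95 ± 0.24), motors of axonal transport, fell and Kif1c rose (1.86 ± 0.15). The kinesin family as a whole, 4 higher and 18 lower of 37, passed as deposited (adjusted p = 0.0221; adjusted p = 0.721 with an estimated correlation) and not after quantile normalization (0.0544). The same held for Nup genes (0 higher and 5 lower of 18; adjusted p = 0.0221, and 0.0544 after quantile normalization; 0.721 with an estimated correlation). It also held for Ube genes (2 higher and 17 lower of 38; 0.0221, 0.0652 and 0.55) and secretoglobin (Scgb) genes (6 higher and 0 lower of 22; 0.0251, 0.0675 and 0.55).

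Several of these families share members with the fixed lists and so are not separate from them. Scgb3a1 (5.11), Scgb3a2 (4.06), Scgb1a1 (1.51) and Cyp2f2 (4.63) are club and secretory cell markers, whose list median was 4.20. Syt1 and Syt4 are neuroendocrine markers, Mapk8ip2 is in the list of neuronal genes repressed by REST, Kif11, Kif20a and Ube2c are mitosis genes, Col4a1 and Col4a2 are basement membrane genes, and Col6a3, Col3a1, Col1a1 and Col1a2 are fibroblast and mural cell markers.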
